A study of Mus musculus with 8 samples.

How the data were processed

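Liver RNA of 8 gnotobiotic mice, 4 colonised with the CC+ and 4 with the CC- community, was made into strand-specific mRNA libraries, 1 per mouse, per the labels' protocols. Per the submitters' processing notes, Bowtie2 and RSEM 1.2.23 were used with the mouse build mm9, and per the file headers the values are RSEM gene results built on RefSeq transcripts. The authors' deposited expected counts are RSEM's estimated reads per gene, which need not be whole because reads that fit several genes are divided among them, and they are not normalized. The authors' deposited TPM values, per the file headers RSEM output, are each gene's share of a library's transcripts after division of the counts by transcript length, scaled to a fixed total. The authors' deposited table of the EBSeq comparison holds, per the file headers, a posterior probability of differential expression and a ratio of the community means with and without shrinkage. Its signal for each library is, as deposited by the authors, a normalized expected count, and it was proportional to the library's expected counts. The table covers 15821 genes, of which 21 names had been turned into dates by a spreadsheet and were not matched. The version of EBSeq and the rule that chose the genes are not given in the sources used here. No genome coordinates are printed, because the reference used here is of another build than the files. It served for gene names, transcript GC content (found for 99.5% of genes) and a blastn 2.17.0 search for near-identical transcripts (at least 98% identity over at least 50% of the length) of Tgtp1, Amd2 and the 52 genes at a posterior probability of 0.95 or more in the authors' deposited table, of which 51 had a matched transcript. Other genes were not searched for copies.

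Samples were grouped by the community named in the labels, and replicate numbers were taken from the sample titles. Before the data were examined, the tests, gene lists, named-gene rule and alternatives were fixed. Expected counts were rounded to whole numbers. Genes were kept by filterByExpr, and libraries were scaled by TMM in edgeR 4.0.16 under R 4.3.3. The quasi-likelihood test with robust dispersion gave CC+ minus CC- log2 fold changes, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors are the size of the log2 fold change divided by the root of the test's F. The biological coefficient of variation was 17.6%. CPM values are counts divided by the TMM-scaled library size and brought to the usual fixed total. Differences in single values per library were tested by an exact two-sided permutation test over the 70 assignments of the 8 libraries, whose smallest p is 0.0286.

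Of 38 gene lists, 36 had at least 5 tested members and were tested by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the lists. The pancreatic acinar list had 1 tested member, and the list and library share of mitochondrially encoded genes were not analysed here. Camera with an estimated correlation and fry were alternatives, and the mean per library was an alternative chosen after seeing the data. Named genes were chosen as genes past the threshold without overlap between communities, up to 12 in each direction, the 10 genes with the smallest p because fewer than 10 passed, 20 fixed genes of choline, methyl and lipid metabolism, the 4 members with the smallest p of each called list, and up to 4 highly expressed genes called in the authors' deposited table alone. Results of some of these genes are not reported here. Amy2a5, Pnlip, Cfd, Rps27, Amd1, Cela1, Tgtp1, the clock genes, Irgm2, Gbp2, Gbp3, Gbp6 and the genes that separate replicates 1 and 2 from 3 and 4 were chosen after their values were seen.

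The tests were checked on simulated counts with 200 changed genes drawn from the means and depths of this comparison. The edgeR fit recovered 10.5% of genes changed 1.5-fold, 74% of those changed 2-fold and 95% of those changed 3-fold, with 1, 7 and 14 false calls among 11952, 11973 and 11963 tested genes. A simulated list of independent genes changed 1.3-fold was called, with 0 of 35 other lists. All genes were simulated as independent, so this check does not show how often lists of correlated genes are called falsely. Alternatives covered size factors (RLE), no scaling beyond totals, filters, DESeq2 1.42.0, limma-voom with and without sample weights, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1, a block for the replicate number, each library left out in turn, an adjusted p under 0.10 and a minimum fold of 1.2. Alternatives chosen after seeing the data removed each library's loess trend (span 0.5) on transcript length, on GC content or on both, summed Tgtp1 with Tgtp2, used DESeq2 without independent filtering, on genes with at least 1 count or on all genes, and set replicates 1 and 2 against 3 and 4 as a block. Libraries were compared in pairs for duplicates, and the chi-square of their counts per degree of freedom was at least 17.2 in every pair, so none was counted as a repeat of another.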

Results

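Liver messenger RNA was sequenced from 8 female C57BL/6J mice that were bred germ-free and then colonised for 2 weeks with a defined community of 6 gut bacterial strains while eating a diet with 1% choline. In 4 mice (CC+) the Escherichia coli strain of the community was wild type, and in the other 4 (CC-) the same strain lacked cutC, the gene of the bacterial choline trimethylamine-lyase, which splits choline into trimethylamine and acetaldehyde. The mice were 9 weeks old and had fasted for 4 hours. Each library came from 1 mouse. The labels name no cage, so a cage shared by the mice of a community could not be told apart from the community. The total of expected counts ranged from 11480479 in CC+ replicate 4 to 16370480 in CC+ replicate 3. The files hold 20325 mouse genes, of which 12047 had enough counts to be tested. Because cutC is a bacterial gene, no mouse transcript checks the community label of a library.

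The comparison of CC+ with CC- livers asks whether a choline-consuming bacterial enzyme in the gut was accompanied by a different liver transcriptome. Tgtp2, an interferon-inducible GTPase gene, was the only gene of the 12047 that passed the edgeR quasi-likelihood test, and it was higher in CC+ livers. Its normalised level was 30.0 ± 3.79 CPM (counts scaled to library size) in CC+ and 11.8 ± 1.08 CPM in CC- (mean ± SD, n = 4 each), a ratio of 2.54 and a log2 fold change of 1.35 (SE 0.13) with an adjusted p of 0.00153. All 4 CC+ libraries lay above all 4 CC- libraries. Tgtp2 has a near-identical copy, Tgtp1, with 99.8% identity over 2811 bases, so the division of reads between the pair is uncertain. In CC- libraries 47.6% to 70.2% of the pair's counts were assigned to Tgtp1, against 2.77%, 68.8%, 64.9% and 0.0245% in CC+ replicates 1 to 4. The summed level of both genes was 34.0, 105, 71.3 and 29.0 CPM in CC+ replicates 1 to 4 and 23.6 to 36.0 CPM in CC- libraries. With the counts of Tgtp1 and Tgtp2 summed, a choice made after seeing the data, the log2 fold change was 1.00 (SE 0.40) with an adjusted p of 0.671, and edgeR called 0 genes, with 868 at an unadjusted p under 0.05.

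**Figure D1:**
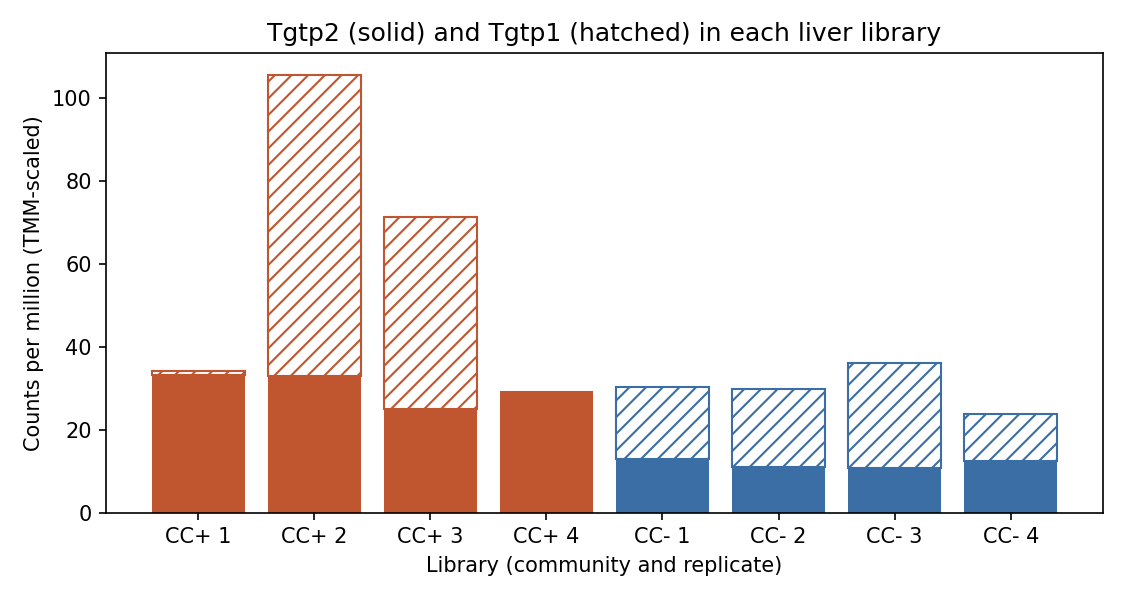
Level in CPM (vertical axis) of Tgtp2 (solid) and of its near-identical copy Tgtp1 (hatched, stacked on top) in each of the 8 liver libraries, CC+ in orange and CC- in blue. The solid bars of all CC+ livers are higher than those of all CC- livers, whereas the stacked heights of CC+ replicates 1 and 4, 34.0 and 29.0 CPM, lie within the 23.6 to 36.0 CPM of the CC- livers.

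No other gene passed in edgeR, where the next smallest adjusted p was 0.672. The genes with the smallest unadjusted p after Tgtp2 were Slc4a4, Tgoln2, March6, Lrp4, Ptpn4, Abcc3, Dnase1l3, Tlr5 and Retsat. Slc4a4, a sodium bicarbonate cotransporter gene, stood at 205 ± 11.9 CPM in CC+ and 116 ± 25.6 CPM in CC- (log2 fold change 0.81, SE 0.15). Tlr5, which encodes the receptor for bacterial flagellin, stood at 8.50 ± 0.384 and 4.40 ± 1.65 CPM (0.95, SE 0.23). The levels of Retsat, a retinol saturase gene, were 305 ± 28.8 and 188 ± 48.1 CPM (0.69, SE 0.17), and those of Lrp4, of the LDL receptor family, 21.4 ± 2.43 and 14.3 ± 1.59 CPM (0.59, SE 0.13). Tgoln2, of the trans-Golgi network, stood at 104 ± 9.22 and 72.5 ± 3.12 CPM, March6, an endoplasmic reticulum ubiquitin ligase gene, at 193 ± 11.3 and 134 ± 13.2 CPM, and the phosphatase gene Ptpn4 at 9.64 ± 0.753 and 5.83 ± 1.13 CPM. Dnase1l3, which encodes a secreted DNase, was the member of this group with the lower mean in CC+, at 87.6 ± 8.18 against 124 ± 12.1 CPM (-0.50, SE 0.12). For each of these 9 genes the 4 CC+ libraries did not overlap the 4 CC- libraries, an arrangement found for 484 of the tested genes (4.02%, against 2.86% by chance). In all, 867 genes had an unadjusted p under 0.05 in edgeR, 468 with a higher and 399 with a lower level in CC+, where 602 would be expected by chance. DESeq2, with its own filter on mean counts, called 22 genes (15 higher and 7 lower in CC+), among them Slc4a4, Tgoln2, March6, Abcc3, Abcb4, Retsat, Hadhb, Lonp2, Dnase1l3, S100a10 and Hspe1. That filter gave Tgtp2 no adjusted p, and without it DESeq2 called 5 genes, Tgtp2, Slc4a4, Tgoln2 and March6 among them.

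Of the 20 genes of choline, methyl group and lipid metabolism fixed in advance, none passed the edgeR test. Chdh, which starts choline oxidation in the liver, stood at 216 ± 24.8 CPM in CC+ and 192 ± 16.8 CPM in CC- (log2 fold change 0.17, SE 0.12). Bhmt, which uses the betaine formed from choline to make methionine, stood at 3223 ± 249.9 and 3746 ± 847 CPM (-0.22, SE 0.16). The mean of Gnmt, a glycine methyltransferase gene whose enzyme uses S-adenosylmethionine, was 959 ± 109.6 CPM in CC+ and 1464 ± 368 CPM in CC-, without overlap between the communities (-0.61, SE 0.17, adjusted p = 0.672). Mat1a, which makes S-adenosylmethionine, differed by 0.045 (SE 0.17), Pemt, which methylates phosphatidylethanolamine to phosphatidylcholine, by -0.31 (SE 0.17), and Cbs by 0.11 (SE 0.12). The DNA methyltransferase genes Dnmt1 and Dnmt3a differed by 0.022 (SE 0.13) and 0.14 (SE 0.13). Chka, whose product phosphorylates choline, had a log2 fold change of -0.40 (SE 0.14), Pcyt1a 0.11 (SE 0.10) and the choline transporter gene Slc44a1 -0.11 (SE 0.14). Among the lipid genes, Apob stood at 5592 ± 1073 CPM in CC+ and 3794 ± 1053 CPM in CC- (0.56, SE 0.21), while Mttp differed by 0.15 (SE 0.16) and Scd1 by -0.41 (SE 0.43). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 1.44 with an SE of 0.89, and Fgf21 by 0.14 with an SE of 0.78. Fasn ranged from 208 to 2084 CPM in CC- and from 212 to 1087 CPM in CC+. Leaving out 1 library moved several of these values by over 1.5 times. The log2 fold change then ranged from 0.0067 (without CC+ replicate 1) to 0.28 (without CC- replicate 2) for Mttp. For Scd1 it ranged from -0.86 (without CC+ replicate 1) to -0.022 (without CC- replicate 2). The range was 0.63 (without CC+ replicate 4) to 2.01 (without CC- replicate 4) for Cyp7a1 and -1.93 (without CC+ replicate 1) to -0.22 (without CC- replicate 2) for Fasn. For Bhmt it was -0.33 (without CC- replicate 1) to -0.063 (without CC- replicate 4), and for Pemt -0.41 (without CC- replicate 3) to -0.12 (without CC- replicate 2). Slc44a1 ranged from -0.24 (without CC+ replicate 1) to -0.037 (without CC+ replicate 2). Chdh ranged from 0.089 (without CC+ replicate 1) to 0.22 (without CC- replicate 3). The range was 0.078 (without CC- replicate 4) to 0.24 (without CC- replicate 3) for Dnmt3a. For Cbs it was 0.060 (without CC- replicate 1) to 0.16 (without CC+ replicate 3). The signs of Fgf21, Mat1a and Dnmt1 turned.

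Gene lists were compared with the remaining genes by camera with a preset correlation of 0.01 between genes, which called 8 of 36 lists, 3 higher and 5 lower in CC+. The fatty acid oxidation, ketogenesis and PPAR-alpha list was higher in CC+, with 38 of 39 tested members above 0, a median log2 fold change of 0.42 and an adjusted p of 5.42e-19 (adjusted p = 0.665 with an estimated correlation). Its members with the smallest p were Hadhb and Hadha, which encode the subunits of the mitochondrial trifunctional protein of beta-oxidation, Etfdh and the ketone body enzyme gene Bdh1. Hadhb stood at 275 ± 12.5 CPM in CC+ and 209 ± 21.6 CPM in CC-, Hadha at 321 ± 36.6 and 252 ± 22.1 CPM, Etfdh at 393 ± 15.7 and 289 ± 55.7 CPM, and Bdh1 at 320.3 ± 28.3 and 249 ± 18.1 CPM. No member of this list passed when adjusted over the list alone (0 of 39 by edgeR, with 13 at an unadjusted p under 0.05). The bile acid list was higher, with 20 of 28 members above 0 and a median of 0.18 (adjusted p = 3.33e-04, and adjusted p = 0.665 with an estimated correlation). Within it Abcc3, an export pump gene for bile salts and glucuronides, stood at 239 ± 38.1 and 163 ± 7.17 CPM, and Abcb4, the canalicular phosphatidylcholine transporter gene, at 292 ± 24.5 and 192 ± 40.5 CPM. These 2 genes passed when adjusted over the list alone. Klb, the coreceptor gene of FGF15 and FGF21 signalling, stood at 57.1 ± 5.92 and 42.5 ± 6.00 CPM, and the uptake transporter gene Slco1b2 at 1509 ± 106 and 1068 ± 247 CPM. The interferon response and antigen presentation list was higher, with 34 of 41 members above 0 and a median of 0.24 (adjusted p = 5.18e-05, and adjusted p = 0.749 with an estimated correlation). Its members with the smallest p were Cxcl10 (log2 fold change 0.92, SE 0.33), Igtp (0.81, SE 0.29), Irgm1 (0.42, SE 0.17) and Iigp1 (0.58, SE 0.24), and none passed when adjusted over the list alone (0 of 41 by edgeR, with 5 at an unadjusted p under 0.05). Igtp was at 132 and 109 CPM in CC+ replicates 2 and 3 but at 52.1 and 55.1 CPM in CC+ replicates 1 and 4, against 41.3 to 55.8 CPM in CC-. Without CC+ replicate 2 the log2 fold changes of Cxcl10, Igtp and Irgm1 were 0.52, 0.54 and 0.25, and without CC- replicate 2 that of Iigp1 was 0.38. The interferon list was not called without CC+ replicate 2 (median 0.090, adjusted p = 0.26) or without CC- replicate 4 (0.17, adjusted p = 0.071), and its median was 0.38, 0.36 and 0.42 without CC+ replicate 1, CC+ replicate 4 and CC- replicate 1.

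Lists with lower values in CC+ covered lipid synthesis, respiration and markers of other cell types. The cholesterol synthesis and sterol response list had 21 of 25 members below 0 and a median of -0.45 (adjusted p = 5.09e-11, and adjusted p = 0.665 with an estimated correlation). Among its enzyme genes, Idi1 stood at 119 ± 32.9 CPM in CC+ and 189 ± 51.0 CPM in CC-, Fdft1 at 53.2 ± 10.7 and 73.0 ± 16.3 CPM, Tm7sf2 at 72.5 ± 8.96 and 97.8 ± 25.3 CPM, and Mvk at 6.68 ± 0.899 and 9.68 ± 2.17 CPM. The fatty acid and triglyceride synthesis list had 24 of 29 members below 0 and a median of -0.41 (adjusted p = 4.93e-06, and adjusted p = 0.749 with an estimated correlation). Pnpla3 stood at 6.80 ± 3.09 and 20.2 ± 10.03 CPM, and Thrsp at 155 ± 91.9 and 475 ± 363 CPM, while Elovl2, whose product elongates polyunsaturated fatty acids, had the higher mean in CC+ at 832 ± 37.6 against 677 ± 92.0 CPM. Without CC- replicate 2 this synthesis list had a median of -0.14 and was not called (adjusted p = 0.0528), and without CC+ replicate 2 its median was -0.24. Without CC- replicate 2 the log2 fold change of Thrsp went from -1.61 to -1.004 and that of Tm7sf2, of the sterol list, from -0.43 to -0.28. The nuclear-encoded oxidative phosphorylation list had 43 of 47 members below 0 and a median of -0.17 (adjusted p = 8.98e-07, and adjusted p = 0.749 with an estimated correlation), with Atp5h, Ndufv2, Uqcrb and Cycs at -0.30, -0.30, -0.28 and -0.26 (Uqcrb at -0.18 without CC- replicate 3). With each library's trend on transcript length removed, a choice made after seeing the data, the oxidative phosphorylation median was -0.03 and its adjusted p 0.497. On the log2(TPM + 1) scale that median was -0.088, and without CC- replicate 2 it was -0.11. In the sterol, synthesis and oxidative phosphorylation lists 0 members passed in edgeR when adjusted over the list alone, with 9, 4 and 4 at an unadjusted p under 0.05.

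Marker genes of endothelial and erythroid cells had lower values in CC+ beside these lists. The endothelial list had 21 of 23 members below 0 and a median of -0.21 (adjusted p = 2.44e-07, and adjusted p = 0.665 with an estimated correlation), and 4 members passed when adjusted over the list alone. These were Dnase1l3, Ehd3 (121 ± 10.1 against 158 ± 15.0 CPM), Emcn (5.17 ± 0.279 against 7.24 ± 0.982 CPM) and Gpihbp1 (31.3 ± 5.40 against 42.2 ± 3.49 CPM). The erythroid list had 9 of 9 members below 0 and a median of -0.60 (adjusted p = 1.34e-04, and adjusted p = 0.665 with an estimated correlation), with 0 past in edgeR when adjusted over the list alone and 3 at an unadjusted p under 0.05. Alas2, the erythroid gene of haem synthesis, stood at 13.2 ± 1.496 and 20.03 ± 6.71 CPM. The globin genes Hba-a1 and Hba-a2, whose similar sequences leave the division of reads uncertain, stood at 222 ± 71.9 and 474 ± 276 CPM and at 20.1 ± 4.36 and 26.8 ± 9.08 CPM, and Hbb-b2 at 42.4 ± 17.7 and 75.5 ± 21.1 CPM. Without CC- replicate 1 the log2 fold change of Alas2 went from -0.60 to -0.39 and that of Hba-a1 from -1.09 to -0.69. That of Hba-a2, -0.41, ranged from -0.63 (without CC- replicate 3) to -0.28 (without CC- replicate 4). Single libraries or the scale moved the median by over 1.5 times for erythroid cells (-0.33 without CC+ replicate 1, -0.38 without CC- replicate 1), for endothelial cells (-0.12 without CC+ replicate 2, -0.13 on the log2(TPM + 1) scale) and for fatty acid oxidation (0.64 without CC- replicate 4). With an estimated correlation camera called 0 lists, and fry's test for a shift in 1 direction called 0 (lowest adjusted p 0.605).

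**Figure D2:**
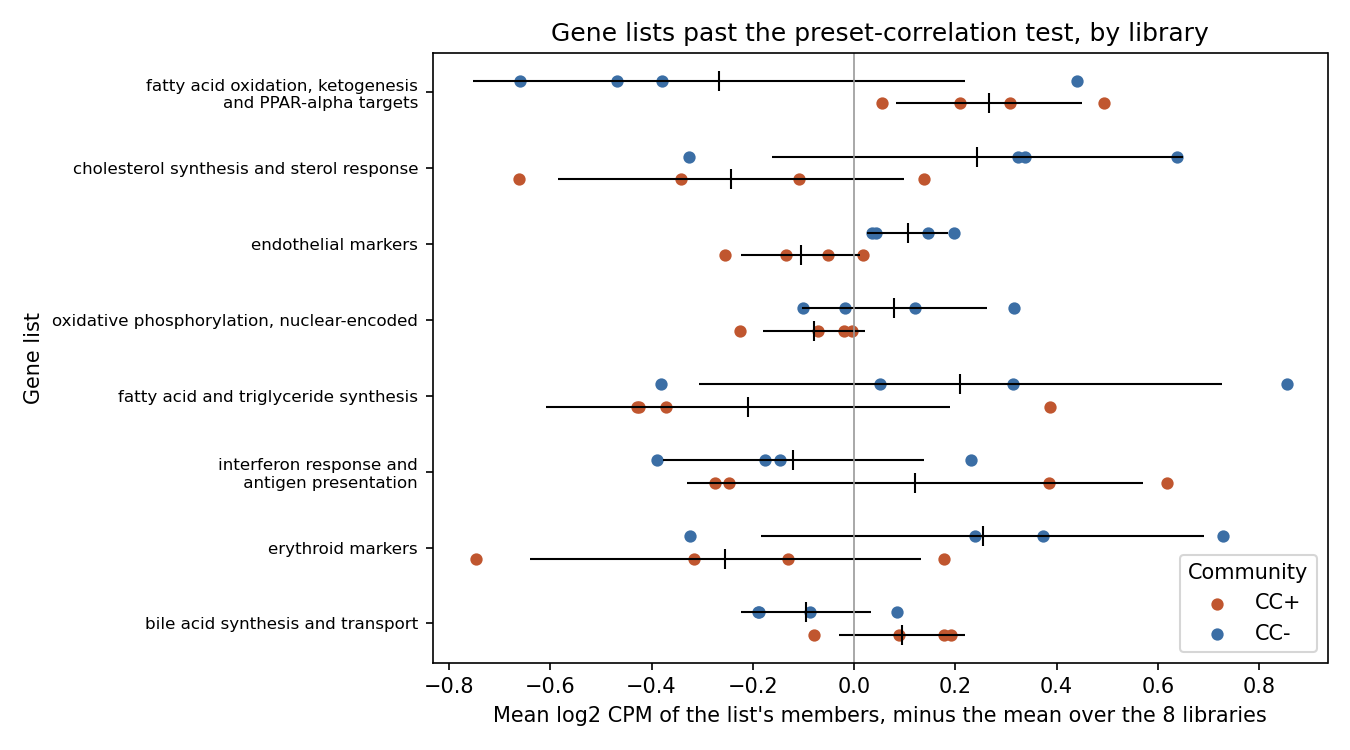
Mean log2 CPM of the members of each of the 8 lists called with a preset correlation, minus the mean over the 8 libraries, for CC+ (orange) and CC- (blue), with 1 point per liver, vertical marks for the means and bars of 1 SD on each side. The communities overlap in every list except the endothelial markers, and for fatty acid oxidation 1 CC- liver, replicate 4, lies among the CC+ livers.

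The other 28 lists did not pass, with medians from -0.18 to 0.26 and adjusted p from 0.122 to 0.985. In the choline oxidation and methionine-folate list 15 of 32 members lay above 0 (median -0.018, adjusted p = 0.47), and in the list of phosphatidylcholine synthesis and choline transport 11 of 27 (median -0.084, adjusted p = 0.481, and -0.018 without CC- replicate 1). The flavin monooxygenases (median 0.054, adjusted p = 0.739), the DNA and histone methylation enzymes (median 0.044, adjusted p = 0.127) and the imprinted genes (adjusted p = 0.921) did not pass. The adjusted p was 0.122 for lipoproteins and lipid uptake and for pericentral hepatocyte markers, 0.127 for female-biased liver genes, 0.146 for heat shock and for the acute phase response, and 0.299 for immediate early genes. It was 0.431 for male-biased liver genes and for the cell cycle, 0.432 for glucose metabolism, 0.774 for inflammatory cytokines, 0.768 for iron and hepcidin, 0.9 for xenobiotic metabolism and 0.921 for the unfolded protein response. NRF2 targets, amino acid catabolism, adipocyte markers and Kupffer cell and macrophage markers stood at 0.495, neutrophil, stellate cell and T, NK and B cell markers at 0.47, and cholangiocyte markers at 0.366. Periportal hepatocyte markers and the circadian clock list both stood at 0.985. Of the 20 tested clock genes 7 had an unadjusted p under 0.05 in edgeR, against 7.20% of all tested genes. Among them Dbp (1.39), Nr1d1 (0.60), Nr1d2 (0.50) and Rora (0.52) had higher and Arntl (-0.39) and Per2 (-0.74) lower log2 values in CC+. Dbp had low levels, at 0.558 to 1.32 CPM in CC- and 1.36 to 1.68 CPM in CC+ except 4.62 CPM in CC+ replicate 3. In edgeR 0 of the clock genes passed when adjusted over the list alone. Camera looks for a shift in 1 direction, so opposite moves within the clock list cancel, and its 0.985 does not speak against a change of these genes. Fry's test for changes in either direction gave this list a p of 0.0413, not adjusted over the lists. That p was smaller for the bile acid (0.00165), endothelial (0.00206), pericentral (0.0262) and lipoprotein (0.0331) lists. For the unfolded protein response and periportal lists the median lay below 0 and the test's direction was up, and for xenobiotic metabolism the mean lay below 0 and the median above. In the heat shock list Hspe1, a mitochondrial chaperonin gene, was the 1 member that passed when adjusted over the list alone, at 109 ± 2.42 CPM in CC+ and 148 ± 18.1 CPM in CC-.

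Of these 28 lists, 14 passed in at least 1 other setting. The methylation enzymes passed without CC- replicate 3 (median 0.12, adjusted p = 0.0116) and with the GC trend removed (0.072, adjusted p = 0.038). Lipoproteins and lipid uptake passed without CC+ replicate 4, CC- replicate 1, CC- replicate 2 or CC- replicate 4 (medians 0.12, 0.095, 0.12 and 0.12). This list also passed with the length trend, the GC trend or both removed (0.095, 0.071 and 0.12). Pericentral markers passed without CC+ replicate 2 or CC- replicate 2 (0.15 and 0.12) and with the same trends removed (0.076, 0.11 and 0.11). The acute phase response passed without CC+ replicate 1, CC+ replicate 3 or CC- replicate 2 (0.15, 0.19 and 0.18) and with the length trend or both trends removed (0.16 and 0.16). Female-biased genes passed without CC+ replicate 1, CC+ replicate 4 or CC- replicate 4 (0.32, 0.20 and 0.23) and with the length trend removed (0.22). The cell cycle list passed without CC+ replicate 1, CC+ replicate 4 or CC- replicate 1 (0.52, 0.58 and 0.43), whereas its median was -0.18 without CC+ replicate 2. Male-biased genes passed without CC+ replicate 1 or 3 (0.18 and 0.24), and glucose metabolism without CC+ replicate 1 or CC- replicate 1 (-0.16 and -0.10). Kupffer cell markers passed without CC+ replicate 2 or CC- replicate 3 (-0.17 and -0.21), and heat shock without CC+ replicate 2 and on the log2(TPM + 1) scale (-0.17 and -0.11). Passing in 1 setting each were immediate early genes (-0.29 without CC+ replicate 2), inflammatory cytokines (0.15 without CC+ replicate 1), T, NK and B cell markers (-0.25 without CC+ replicate 3) and cholangiocyte markers (-0.24 without CC- replicate 4).

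Library measures did not separate the communities. The difference in total was -47104 counts, the share of the 10 most abundant genes was 21.1% ± 1.15 in CC+ and 22.2% ± 2.41 in CC-, and 11092 ± 125 and 11040.2 ± 209.9 genes had a TPM of at least 1. In the exact two-sided permutation test the p was 0.971, 0.543 and 0.714 (adjusted 0.971 for each). Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.972 to 0.987 within communities and 0.970 to 0.988 between them. Log2 fold changes rose with transcript length across genes (Spearman rho 0.345), with a median length of 4421 bases for genes at an unadjusted p under 0.05 and higher in CC+, against 1585 bases for those lower in CC+. For each library, log2 CPM was taken as the deviation from each gene's mean over the 8 libraries. The rank correlation of these deviations with length ranged from 0.00396 to 0.243 in CC+ and from -0.331 to 0.212 in CC-. These values are thus relative to the other libraries. The community means did not differ in the exact permutation test (p = 0.0857).

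Larger divisions ran across the communities. Replicates 1 and 2 of both communities stood apart from replicates 3 and 4, and edgeR called 21 genes between these sets of 4 libraries, 7 higher and 14 lower in replicates 1 and 2. This division was picked after seeing the data as the one with the most calls among the 35 divisions of the libraries into sets of 4. Another of them, CC+ replicate 1 with CC- replicates 1 to 3 against the other 4 libraries, does not follow the replicate numbers and gave 20 genes, with 1403 at an unadjusted p under 0.05 against 1629 for replicates 1 and 2 against 3 and 4. Per1, a core clock gene, stood at 4.52 ± 0.738 CPM in replicates 1 and 2 and 14.8 ± 2.28 CPM in replicates 3 and 4 (log2 difference -1.71, SE 0.16, adjusted p = 9.6e-04). The kinase gene Clk1 stood at 23.7 ± 3.14 and 58.7 ± 10.3 CPM, and Ccrn4l, the deadenylase gene nocturnin, at 1.44 ± 0.446 and 7.30 ± 2.65 CPM. Junb, an immediate early transcription factor gene, stood at 8.07 ± 1.88 and 2.11 ± 0.720 CPM. The labels name no day, cage or time for the replicate numbers. Within replicates 1 and 2 the difference of CC+ minus CC- in mean log2 CPM was 0.79 for the fatty acid oxidation list and -0.75 for the sterol list, and within replicates 3 and 4 it was 0.27 and -0.22. For oxidative phosphorylation it was -0.34 and 0.022, for fatty acid and triglyceride synthesis -0.60 and -0.23, for endothelial markers -0.31 and -0.11, for erythroid markers -0.84 and -0.18, and for bile acids 0.32 and 0.057. For the interferon list the difference was smaller in replicates 1 and 2, at 0.13 against 0.35. Each of these differences rests on 2 replicates of each community and was not tested. For fatty acid oxidation, CC- replicates 3 and 4 themselves stood at a mean log2 CPM of 6.86 and 7.77.

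**Figure D3:**
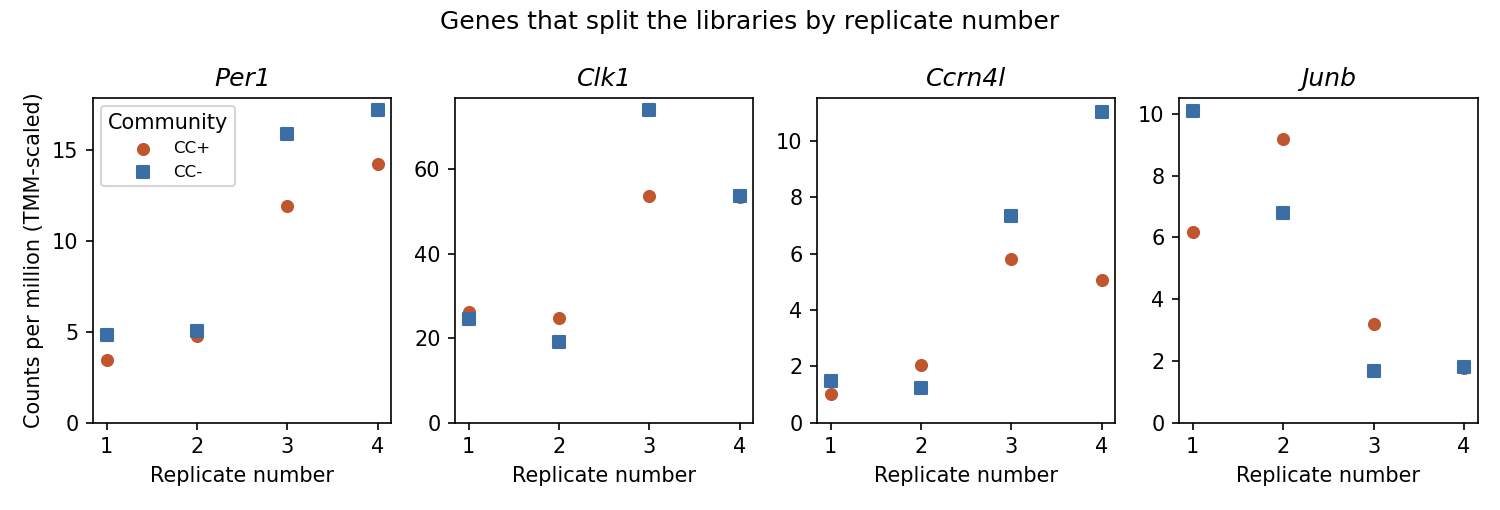
Level in CPM (vertical axes) of Per1, Clk1, Ccrn4l and Junb against the replicate number (horizontal axes) in the sample titles, for CC+ (orange circles) and CC- (blue squares), with 1 liver per point. In both communities Per1, Clk1 and Ccrn4l are lower and Junb is higher in replicates 1 and 2 than in replicates 3 and 4.

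The authors' deposited table of an EBSeq comparison rests on the same 8 libraries, so it is not independent evidence. At a posterior probability of 0.95 or more, the authors' deposited table lists 52 genes, 28 higher and 24 lower in CC+, and 39 at 0.99 or more. Of the 52, 47 were tested and Tgtp2 was also called by edgeR. Across 12031 genes the log2 fold changes of the authors' deposited table and of the edgeR fit had a Spearman correlation of 0.999. Among the highly expressed genes called in the authors' deposited table and not by edgeR were Retsat, the calcium-binding protein gene S100a10 (163 ± 17.4 CPM in CC+ and 227 ± 22.6 CPM in CC-), Hspe1 and the peroxisomal protease gene Lonp2 (370.1 ± 19.2 and 269 ± 31.3 CPM). For 5 of the 52 genes of the authors' deposited table over 90% of the signal came from 1 library. These were the pancreatic enzyme genes Amy2a5 and Pnlip, with 571 and 76 expected counts in CC+ replicate 4 and 0 in the other libraries, Cfd, with 78 in CC- replicate 2, Rps27, with 264 in CC- replicate 3, and Amd1. Amy2a5, Rps27 and Amd1 have near-identical copies, for Rps27 Gm9846 and for Amd1 Amd2. Amd1 held 362 counts in CC- replicate 1, where Amd2 held 1.5, and under 1 count in every other library.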

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

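Of the tests in this part, those of the summed Tgtp1 and Tgtp2 counts, of the GTPase genes, of the hepatocyte share, of the oxidative phosphorylation and erythroid lists taken singly, and of the length trend across divisions and within communities were chosen only after the result was seen.

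Among 150 groups of 4 livers, 11 had 1 liver far from the other 3, measured as its gap to the nearest other divided by the range of the group, and chance gives 7.5. CC+ replicate 1 stood apart for Fasn (1087 CPM against 212 to 293 in the other CC+ livers, ratio 0.908), Thrsp (292 against 104 to 117 CPM, ratio 0.927), Mttp (607 against 418 to 447 CPM, ratio 0.848), the fatty acid and triglyceride synthesis list (mean log2 CPM 8.04 against 7.22 to 7.28, ratio 0.931) and the share of the 10 most abundant genes (22.9% against 20.5% to 20.6%, ratio 0.948). CC+ replicate 2 stood apart for Retsat (348 against 287 to 294 CPM, ratio 0.884) and Bhmt (3595 against 3064 to 3141 CPM, ratio 0.853), and CC+ replicate 4 for Slco1b2 (1667 against 1445 to 1468 CPM, ratio 0.896). In CC-, replicate 2 stood apart for Mttp (541 against 376 to 403 CPM, ratio 0.836) and S100a10 (261 against 213 to 219.5 CPM, ratio 0.859), and replicate 4 for March6 (154 against 127 to 128 CPM, ratio 0.946).

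Genes of the pancreatic acinar list, which is outside the comparison, summed to 115 CPM by library total in CC+ replicate 4 and to 5.48 to 14.5 in the other 7 libraries, with counts for 21 of the 23 genes against at most 5. Amy2a5 held 571 of these counts and Cela1, which had 80 to 200.3 counts in the other libraries, held 166.

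Tgtp2 was higher in all 4 CC+ livers, and reads shared with Tgtp1 are a candidate explanation of its separation. With the counts of the pair summed, the log2 fold change went from 1.35 (SE 0.13) to 1.00 (SE 0.40) and the adjusted p to 0.671, as the sum varied more between CC+ livers than Tgtp2 did. A difference of the related genes Iigp1, Igtp, Irgm1, Irgm2, Gbp2, Gbp3 and Gbp6 as a group cannot be told apart, because their median log2 fold change of 0.60 (0.42 to 0.81) lay under the Tgtp2 value by over 2 SE but within 2 SE of that of the summed pair. By liver, the summed pair was highest in CC+ replicates 2 and 3, as were Igtp, Irgm1 and Iigp1 of the group. In CC+ replicates 1 and 4 the sum, 34.0 and 29.0 CPM, lay within the range of the CC- livers. Their higher Tgtp2 thus rests on the division of reads within the pair. At least 1 gene was called in 7 of the 35 divisions of the 8 libraries into sets of 4 (highest other 21), so chance cannot be excluded for the count of 1. A response of the pair to the community stays open, untested.

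The called lists, with fatty acid oxidation higher and sterol synthesis lower, are weighed as 1 pattern. At least 8 lists were called in 31 of the 35 divisions (highest other 21), and the 867 genes at an unadjusted p under 0.05 were matched or exceeded in 8 (highest other 1629), so chance cannot be excluded for either count. The 1629 belong to replicates 1 and 2 against 3 and 4, and the 35 divisions take no account of these sets. With these sets as a block, chosen after seeing the data, 1086 genes were at an unadjusted p under 0.05 in edgeR, a count not compared across divisions. Removing the length trend was a choice made after seeing the data. It left at least 0.986 of the medians of both lists and 0.946 of the erythroid median, which argues against transcript length for these. It left 0.179 of the oxidative phosphorylation median, which length may account for. A test of the oxidative phosphorylation and erythroid lists together was written after the list results but before its own outcome was seen. It asked whether both medians shrank, and the erythroid one did not. By that test length was not the account of both lists together. A lower share of hepatocyte RNA in CC- is argued against as the whole cause, although the endothelial, stellate, Kupffer and cholangiocyte medians all lay below 0 (highest -0.0566). It would move hepatocyte genes alike, whereas the sterol median was -0.45 and the medians of amino acid catabolism, -0.020 (SD of members 0.21), and of periportal markers, -0.0068 (SD 0.24), lay under the 0.42 of fatty acid oxidation by more than the spread of their members. Lower values of endothelial genes in CC+ stay open. The community stays among the open explanations, as untested. A cage shared within a community could not be told apart from it. A difference in time of day between the communities also stays open, untested. Of the 20 tested clock genes 7 were at an unadjusted p under 0.05 in edgeR, against 7.20% of all tested genes.

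For the rise of fold change with transcript length, 5 of the 35 divisions gave a rank correlation as large as 0.345 (highest other 0.447), so chance cannot be excluded. The largest difference in length trend between livers of 1 community was 1.96 times the difference of the community means, and the rank correlation was 0.315 with the GC trend removed.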

How the results depend on the processing

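Tgtp2 was called in each of the 24 alternatives that kept it as a separate gene and gave it an adjusted p (log2 fold change 1.27 to 1.43, adjusted p 3.82e-15 to 0.0114), and not with Tgtp1 and Tgtp2 summed, where 0 genes passed and 0 were higher. The edgeR and limma settings with both genes apart called 1 gene each, as did each fit without 1 library. DESeq2 called 22 genes (15 higher, 7 lower), and, in settings chosen after seeing the data, 5 (4 and 1) without independent filtering, 20 (13 and 7) on genes with at least 1 count and 15 (10 and 5) on all genes in the files. Of the 58 other genes covered here, 0 passed in any edgeR or limma setting, whereas DESeq2 called 11. The list count was 0 with an estimated correlation, 0 by fry's test for 1 direction and 10 to 14 without 1 library (14 without CC+ replicate 1). It was 9 on the log2(TPM + 1) scale, 11 with the length trend removed, 11 with the GC trend removed and 10 with both removed. Over all settings 29 of 136 values of the 8 called lists lost the call without a change of direction (8 of them as a mean per library, a test that could pass only if most of the 36 lists reached its smallest p, 0.0286), and 38 of 476 values of the other 28 lists gained it. The estimated correlation was 0.148 to 0.602 in the 8 called lists, against the preset 0.01, so their calls rest on that preset. What caused the other changes was not tested, except that leaving out a library or summing the pair alters the data themselves. Of simulated genes changed 1.5-fold, 10.5% were recovered, and which of depth, the number of livers and their variation limits this was not tested.

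Whether replicate numbers pair the samples is not settled, because the correlations of deviations between same-numbered libraries were not tested. They were -0.127, -0.0532, 0.0129 and 0.301, and only number 4 exceeded its best other number (0.147). The fit with the replicate block called 1 gene and 8 lists.

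In 78 values, none called in either fit, the sign turned, and the cause was not tested. All are log2 medians or fold changes. On the log2(TPM + 1) scale they were 0.026 for choline oxidation, 0.011 for phosphatidylcholine synthesis, 0.047 for imprinted genes, 0.032 for NRF2 targets, 0.033 for circadian clock, 0.051 for glucose metabolism, 0.066 for amino acid catabolism, 0.10 for unfolded protein response, 0.031 for iron and hepcidin, 0.089 for periportal markers, 0.034 for Kupffer cells and 0.027 for stellate cells. With the replicate block they were 0.00062 for amino acid catabolism, 0.030 for unfolded protein response and 0.044 for periportal markers. With replicates 1 and 2 against 3 and 4 as a block they were 1.76e-05 for imprinted genes and 0.025 for periportal markers. The mean per library gave 0.021 for imprinted genes, -0.016 for xenobiotic metabolism, 0.011 for unfolded protein response and 0.018 for periportal markers. With the length trend removed they were -0.068 for Dnmt1, -0.0069 for Dnmt3a, -0.024 for methylation enzymes, 0.0070 for imprinted genes, 0.053 for unfolded protein response, 0.041 for periportal markers and 0.0014 for T, NK and B cells, with the GC trend removed 0.0012 for choline oxidation, 0.023 for unfolded protein response and 0.0077 for periportal markers, and with both removed -0.034 for Dnmt1, 0.019 for NRF2 targets, 0.011 for unfolded protein response and 0.048 for periportal markers. Without 1 library the values ranged over -0.048 to 0.068 for Dnmt1, -0.21 to 1.19 for Fgf21, -0.074 to 0.17 for Mat1a, -0.21 to 0.20 for Kupffer cells, -0.13 to 0.038 for NRF2 targets, -0.25 to 0.063 for T, NK and B cells, -0.094 to 0.024 for amino acid catabolism, -0.18 to 0.58 for cell cycle, -0.056 to 0.031 for choline oxidation, -0.070 to 0.046 for circadian clock, -0.012 to 0.32 for female-biased genes, -0.010 to 0.086 for flavin monooxygenases, -0.16 to 0.033 for glucose metabolism, -0.080 to 0.072 for imprinted genes, -0.055 to 0.15 for inflammatory cytokines, -0.10 to 0.24 for male-biased genes, -0.31 to 0.00066 for neutrophils, -0.078 to 0.10 for periportal markers, -0.12 to 0.036 for stellate cells, -0.072 to 0.11 for unfolded protein response and -0.0022 to 0.11 for xenobiotic metabolism.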

Other observations

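The tests of the time of day and of depth, and the division of the libraries that they address, were chosen only after the result was seen. Further genes divided replicates 1 and 2 from replicates 3 and 4 in both communities. Hhex, a transcription factor gene, stood at 29.3 ± 6.32 CPM in replicates 1 and 2 and 62.6 ± 6.03 CPM in replicates 3 and 4 (mean ± SD, n = 4 each), Errfi1, an inhibitor gene of EGF receptor signalling, at 459.9 ± 111 and 1315 ± 337 CPM, and Trp53inp1 at 51.1 ± 17.2 and 134 ± 18.3 CPM. The kinase gene Clk4 stood at 10.8 ± 0.843 and 19.5 ± 1.23 CPM, and Ogt, the O-GlcNAc transferase gene, at 28.7 ± 2.68 and 49.7 ± 10.5 CPM. In the other direction, Osgin1 stood at 155 ± 24.7 and 68.2 ± 12.4 CPM, Hes1 at 10.997 ± 2.93 and 4.88 ± 0.531 CPM, and Pim1 at 15.6 ± 0.595 and 8.60 ± 0.780 CPM. These 8 genes were among the 21 that passed the edgeR test, whose highest adjusted p was 0.0424.

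A candidate explanation is that replicates 1 and 2 were collected at another time of day than replicates 3 and 4. Of the 20 tested clock genes, 8 (40%) had an unadjusted p under 0.05 in this division, against 13.5% of all tested genes, Per1, Nr1d2 (44.3 ± 13.1 and 63.7 ± 9.87 CPM) and Npas2 (21.7 ± 6.43 and 12.1 ± 4.31 CPM) among them. Nr1d1, also among the 8, moved opposite to Nr1d2 (70.7 ± 23.2 and 47.6 ± 13.0 CPM). The test is not specific to this division, since 7 of the 20 were at an unadjusted p under 0.05 between the communities, against 7.20% of all tested genes there. The same candidate thus stays open for the communities. Feeding, handling and cage were not tested. A difference in depth cannot be told apart, because the totals of replicates 3 and 4 lay below all of those of replicates 1 and 2 except in CC+ replicate 3, which had the highest of all (exact permutation p = 0.229). With this division as a block, a setting chosen after seeing the data, edgeR called 1 gene and camera 8 lists.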
